A study of Rattus norvegicus with 16 samples.

How the data were processed

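RNA from the right ventricular wall of male Wistar rats with a body weight of 160 to 180 g was hybridised to 16 Affymetrix arrays, 1 per sample. Per the labels' protocols, labelled cDNA was made from 500 ng of total RNA, without depletion of ribosomal RNA, with a kit that labels the sense strand of whole transcripts with biotin. The samples were grouped by the condition in their labels into 7 CON, 5 RVF+ and 4 RVF arrays, and are named here by group and by the number in their title (CON 1 to 7, RVF+ 8 to 12, RVF 13 to 16). The labels give no batch, date or pairing.

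The authors deposited 1 intensity per probe set and array, summarised by RMA (robust multi-array average, a background correction, quantile normalization and probe summary) per the submitters' processing notes. The software, its version, the array build and the genome build are not given in the sources used here, and no coordinates are printed. The deposited intensity values were on a linear scale from 2.202 to 10294, with medians over all probe sets between 27.1 and 29.3 in all arrays, and were converted to log2 before any test. A difference of 1 on that scale is a 2-fold change in intensity. RMA compresses differences of dim probe sets, so a fold change near background is smaller than the change in RNA. No scanner values or detection calls were used here, and the number of arrays limits the precision.

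Of the 29214 probe sets, 18644 were paired with exactly 1 gene symbol by the array annotation, 962 with several, and 9608 were not listed by it. The identifiers of 18460 probe sets matched the RefSeq gene table of assembly GRCr8, and 0 symbols changed. Only probe sets with 1 symbol were tested. For the 879 genes with more than 1 such probe set the one with the highest mean over all arrays was taken, which left 17245 genes, and dim genes were not removed. Kcnip2 was not analysed, since its probe set is shared with another symbol. Second probe sets of Cyp2e1 and Cd4 were near background and showed smaller differences. Hbb is measured beside near-identical copies of the beta-globin gene, so its value is uncertain.

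Group means were fitted to all 16 arrays at once with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3, which gave 13 residual and 4.45 prior degrees of freedom. The 3 groups therefore share 1 estimate of the spread per gene. Each pair of groups was compared, and p-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. All such adjusted p-values are two-sided and come from limma.

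Before the data were examined, 29 gene lists of pathways, cell types and sample quality were written down, with 581 genes of which 523 were measured. Each list was tested in each comparison with limma's camera at a preset inter-gene correlation of 0.01, and adjusted over the 87 tests. Camera asks whether a list moved further than the other genes. Beside it stand camera with a correlation estimated from the data, which allows for members that vary together, camera on ranks, and fry, which asks whether a list's own genes move one way on balance. A list is called changed where the preset test passed. Only the cardiac stress programme in RVF against CON also passed with the estimated correlation, and that p-value is given beside each other call.

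The genes named in the text were chosen by a rule of the same date. It takes, per comparison, the 10 rising and 10 falling genes with the largest change among those that passed and whose higher group mean was at or above the median of all genes (5.57), or, where none passed, the 5 rising and 5 falling genes with the smallest p. It adds the 4 members with the smallest p of each list described, and 14 measured genes of cardiac interest. This gave 156 genes, a part of which is described.

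Alternatives tried were quantile normalization and centring of the deposited values, filters on dim genes, all probe sets, the mean of a gene's probe sets, fits on the compared groups only, trend and robust moderation, array quality weights, a 1.5-fold minimum, and leaving out each array in turn. The comparison of the 2 differences from CON was set beside 100 simulated draws of unchanged groups with a shared control group, and beside all 70 assignments of the controls split into parts of 3 and 4. The procedure was tested on simulated data with 17245 genes. In RVF+ against CON it recovered 80.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 3-fold, with 8 false calls. In RVF against CON it recovered 67.2%, 94.0% and 100%, with 10 false calls, and in RVF+ against RVF 76.1%, 89.6% and 100%, with 12 false calls. Of simulated gene lists, all 20 with a 1.5-fold shift and 0 of 20 without one were called in each comparison. The simulated genes varied independently and no outlying array was simulated. These counts therefore do not show how often lists whose members vary together are called falsely. Robust moderation drew on statmod 1.5.0, and the plots were drawn with matplotlib 3.10.9 in Python 3.11.15.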

Results

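Gene expression was measured in right ventricular wall from 16 samples of male Wistar rats. Rats had either undergone a sham operation or had a band placed around the pulmonary artery, which narrows the vessel and loads the right ventricle with pressure. The labels do not say which sample had which operation. They name 7 samples CON, the controls of the design text, and give the other samples as 5 RVF+ and 4 RVF, names that are not spelled out and are kept here. The title of the series places the study in right ventricular failure under long-lasting pressure load, with attention to clinical symptoms and to diastolic function. Nothing in the labels states that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

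Arrays of CON lay apart from all others on the first principal component, which held 49.8% of the variance across 17245 genes, while PC2 held 10.3%. On PC1 the mean was -25.9 ± 3.18 (SD, n = 7) in CON, 24.1 ± 22.5 (SD, n = 5) in RVF+ and 15.2 ± 3.61 (SD, n = 4) in RVF. Both groups differed from CON (two-sided exact permutation tests, p = 0.00126 over 792 splits for RVF+ and p = 0.00303 over 330 splits for RVF, each the smallest its design allows). RVF+ and RVF were not separated on PC1 (exact p = 0.667 over 126 splits). RVF+ 8 stood apart at 62.9 on PC1 and 34.6 on PC2, while the other RVF+ arrays lay between 4.93 and 22.2 on PC1. Its root mean square difference from the CON mean was 0.711 on the log2 scale, against 0.326 to 0.448 for the other RVF+ and RVF arrays and 0.157 to 0.212 for the CON arrays. Correlations across genes between arrays of a group were 0.989 to 0.994 in CON, 0.962 to 0.991 in RVF+ and 0.991 to 0.993 in RVF. At most 0.00342% of values were identical between any 2 arrays, so no array was a copy of another. Because RVF+ 8 moved with many gene groups below, values without it are given beside the groups called in RVF+.

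**Figure D1:**
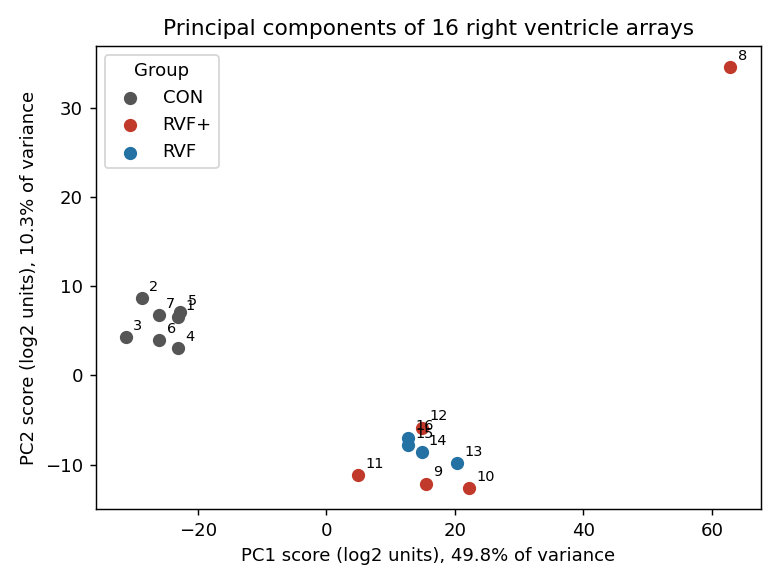
Scores of the 16 arrays on PC1 (horizontal, 49.8% of variance) and PC2 (vertical, 10.3%), in log2 units, 1 point per array with its number and coloured by group. The CON arrays lie between -31.2 and -22.8 on PC1, and RVF+ 8 lies apart from all other arrays at 62.9.

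The first comparison asks how RVF+ ventricles differed from controls. Natriuretic peptide, matrix, growth factor, cell cycle and macrophage genes were higher in RVF+, and genes of mitochondrial fuel oxidation, calcium handling, ion channels and the sarcomere were lower. Nppa, which encodes atrial natriuretic peptide, rose most, by 4.26 ± 0.50 (log2 difference ± SE, here and below), a 19.1-fold difference (adjusted p = 1.14e-05, 5 of 5 RVF+ arrays above all CON arrays). Thbs4 and Postn, which encode the matricellular proteins thrombospondin and periostin, were each 10.4-fold higher (3.38 ± 0.36, adjusted p = 4.76e-06, and 3.37 ± 0.34, adjusted p = 2.69e-06). The largest fall was that of Tmod4, a tropomodulin that caps actin filaments, which was 6.87-fold lower (-2.78 ± 0.52, adjusted p = 0.000645, 5 of 5 below all CON arrays). Its size rested partly on RVF+ 8, without which it was -2.12 ± 0.33. This was a smaller fall than those of Angpt1 and Cacng6 (-2.33 each), Gabrb2 (-2.31), Lsamp (-2.21), Ddit4l (-2.19), Scn4b (-2.17) and Cyp2e1 (-2.13). In all, 2423 genes were higher and 2348 lower, together 27.7% of the genes tested, with 330 higher and 191 lower by at least 2-fold.

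Among the other genes with the largest rise were Ankrd23, a muscle ankyrin repeat protein (9.42-fold), Tceal7 (8.37-fold), the adhesion molecule Ncam1 (6.69-fold), Akip1, a partner of protein kinase A (6.68-fold), Ltbp2, a latent TGF-beta binding protein (6.67-fold), and Nppb, which encodes brain natriuretic peptide (6.48-fold). Their adjusted p-values ran from 3.28e-07 to 1.73e-05, and each lay above all CON arrays in 5 of 5 arrays. Reg3b, a secreted C-type lectin, had a mean 6.96-fold higher but was not uniform (2.80 ± 0.80, adjusted p = 0.0144), with 4 RVF+ arrays above and 1 below all CON arrays. It had 2.04 ± 0.70 without RVF+ 8 (adjusted p = 0.0400) and 3.71 without RVF+ 11. Among the largest falls were the neuronal adhesion molecule Lsamp (5.88-fold lower), the GABA receptor subunit Gabrb2 (5.79-fold), the calcium channel subunit Cacng6 (5.57-fold), Ddit4l, an inhibitor of mTOR signalling (5.49-fold), the sodium channel subunit Scn4b (5.18-fold), the adenylyl cyclase Adcy1 (4.95-fold), Dhrs7c, an enzyme of the sarcoplasmic reticulum (4.91-fold), the vascular growth factor Angpt1 (4.82-fold) and Cyp2e1, a drug-metabolising enzyme (4.75-fold). All of these were below every CON array in 5 of 5 arrays, with adjusted p-values from 4.40e-07 to 4.18e-05.

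The cardiac stress programme rose, with 14 of 19 measured genes higher and 0 lower (15 adjusted over the list alone). Its median log2 difference was 0.80 (camera adjusted p = 3.92e-09, adjusted p = 0.0852 with an estimated correlation), or 0.88 without RVF+ 8, with 15 higher and 1 lower. Ccn2, a connective tissue growth factor, was 4.12-fold higher (2.04 ± 0.16), the skeletal muscle actin Acta1 3.17-fold (1.67 ± 0.19) and Myh7, the slow myosin heavy chain, 1.74-fold (0.80 ± 0.10, adjusted p = 1.58e-05). Myh6, the fast myosin heavy chain of the rodent ventricle, fell by 1.34 ± 0.27 (adjusted p = 0.00125, 5 of 5 below all CON arrays). Without RVF+ 8 its difference was -0.93 ± 0.10 (adjusted p = 2.74e-06).

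Matrix and fibroblast genes rose together. In the extracellular matrix and fibrosis list 32 of 36 genes were higher and 0 lower (34 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 1.27e-19, adjusted p = 0.163 with an estimated correlation). Bgn, which encodes the proteoglycan biglycan, was 2.32-fold higher (1.21 ± 0.09), Col8a1 3.95-fold (1.98 ± 0.16) and the fibronectin gene Fn1 3.31-fold (1.73 ± 0.15). The fibrillar collagens Col1a1 (0.79 ± 0.21, adjusted p = 0.00920) and Col3a1 (0.76 ± 0.17, adjusted p = 0.00304) changed less, each above all CON arrays in 4 of 5 arrays. Of the 14 fibroblast markers 9 rose and 0 fell (9 adjusted over the list alone), among them Thy1 at 3.29-fold, the microfibril gene Mfap5 at 2.49-fold and the activation protease Fap at 2.26-fold (list median 0.44, camera adjusted p = 6.89e-05, adjusted p = 0.0774 with an estimated correlation). In the TGF-beta and growth factor list 14 of 24 genes were higher and 0 lower (16 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 9.84e-08, adjusted p = 0.115 with an estimated correlation). They included the hormone gene Fgf23 (4.62-fold), the ligand Tgfb2 (4.32-fold), the oncostatin M receptor Osmr (2.27-fold) and the activin subunit Inhba (2.08-fold). Without RVF+ 8 the medians of these lists were 0.67, 0.45 and 0.48, with 31, 9 and 14 genes higher. Smooth muscle and pericyte markers had 4 of 11 genes higher and 0 lower (4 adjusted over the list alone), including Mcam (1.77-fold) and Pdgfrb (1.46-fold). Their median of 0.33 (camera adjusted p = 0.0204, adjusted p = 0.358 with an estimated correlation) was 0.18 without RVF+ 8, and the call ended without RVF+ 9 (adjusted p = 0.0620).

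Genes of fatty acid oxidation fell, 28 of 30 being lower and 0 higher (30 adjusted over the list alone), with a median of -0.84 (camera adjusted p = 7.43e-19, adjusted p = 0.232 with an estimated correlation). Ehhadh, a peroxisomal beta-oxidation enzyme, was 2.69-fold lower, Eci1 2.12-fold, the carnitine acetyltransferase Crat 1.89-fold and Hadha, part of the mitochondrial trifunctional protein, 1.84-fold, all in 5 of 5 arrays below CON. All 17 genes of the tricarboxylic acid cycle were lower (17 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 6.37e-09, adjusted p = 0.350 with an estimated correlation), such as the citrate synthase gene Cs (-0.54 ± 0.09, adjusted p = 0.000284) and Ogdh (-0.65 ± 0.11, adjusted p = 0.000393). In oxidative phosphorylation 33 of 43 genes were lower and 0 higher (39 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 5.25e-12, adjusted p = 0.413 with an estimated correlation). Ndufs1 of complex I was 1.56-fold lower, cytochrome gene Cyc1 1.51-fold and the ATP synthase gene Atp5f1a 1.37-fold. Without RVF+ 8 the medians of these lists were -0.68, -0.41 and -0.26, with 28, 16 and 28 genes lower. Ppargc1a, a coactivator of mitochondrial genes, was 1.75-fold lower (-0.81 ± 0.20, adjusted p = 0.00612), with -0.53 without RVF+ 8. Pdk4, which restrains glucose oxidation, had -0.32 ± 0.14 and did not pass (adjusted p = 0.109). Glycolysis and glucose uptake was mixed, 7 of 19 genes being lower and 3 higher (13 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.0103, adjusted p = 0.472 with an estimated correlation), or -0.16 without RVF+ 8. The muscle enzymes Eno3 (2.72-fold) and Pfkm (2.20-fold) and the insulin-responsive glucose transporter Slc2a4 (1.95-fold) were lower. The basal transporter Slc2a1 was 1.33-fold higher (adjusted p = 0.0185), a call that ended without RVF+ 9 (adjusted p = 0.0522) and with median centring (adjusted p = 0.0585). The call of the glycolysis list ended among genes at or above the median level (adjusted p = 0.0692).

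Calcium handling and adrenergic genes fell in 22 of 30 cases and rose in 2 (26 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 1.06e-07, adjusted p = 0.234 with an estimated correlation). The adrenergic receptor gene Adra1b was 2.39-fold lower, the phosphodiesterase Pde3a 1.90-fold, the phosphatase inhibitor Ppp1r1a 1.71-fold, the junctophilin Jph2 1.67-fold and Atp2a2, the calcium pump of the sarcoplasmic reticulum, 1.42-fold (-0.51 ± 0.10, adjusted p = 0.00125). Of 19 cardiac ion channel and connexin genes 12 fell and 2 rose (14 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 2.55e-05, adjusted p = 0.310 with an estimated correlation). Potassium channel genes Kcnd3 (2.35-fold) and Kcnh2 (2.08-fold) and the connexin gene Gja1 (1.82-fold) were lower. Sarcomere genes fell in 12 of 24 cases and rose in 2 (20 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.000114, adjusted p = 0.413 with an estimated correlation). Fhl2 (-0.58 ± 0.09) and the titin gene Ttn (-0.37 ± 0.10, adjusted p = 0.00882) were lower, and the tropomyosin Tpm3 was 2.10-fold higher (1.07 ± 0.13, but 0.61 at its dimmer probe set). Without RVF+ 8 the medians of these lists were -0.41, -0.58 and -0.20, with 19, 12 and 12 genes lower.

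Cell cycle and proliferation genes rose in 22 of 25 cases and fell in 0 (23 adjusted over the list alone), with a median of 1.12 (camera adjusted p = 2.00e-09, adjusted p = 0.413 with an estimated correlation). The median was 0.70 without RVF+ 8, again with 22 genes higher. The proliferation marker Mki67 was 3.38-fold higher (1.76 ± 0.37, adjusted p = 0.00161, and 1.26 ± 0.20 without RVF+ 8), and the mitosis genes Prc1 (2.98-fold) and Aurkb (2.97-fold) were above all CON arrays in 4 of 5 arrays. Macrophage and monocyte markers rose in 15 of 18 cases and fell in 0 (16 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 3.92e-09, adjusted p = 0.323 with an estimated correlation), or 0.80 with 14 higher without RVF+ 8. The mannose receptor Mrc1 was 2.80-fold higher and the complement genes C1qa and C1qc 2.41-fold and 2.27-fold. Interferon response genes rose in 5 of 17 cases (5 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.00553, adjusted p = 0.504 with an estimated correlation), or 0.31 with 3 higher without RVF+ 8. The genes that rose included Isg15 at 1.52-fold (adjusted p = 0.0194, but 0.0709 with array weights) and Oas1a at 1.48-fold (adjusted p = 0.00466). Red cell genes rose in 4 of 8 cases (4 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 0.00764, adjusted p = 0.452 with an estimated correlation), 0.80 without RVF+ 8 and 0.35 without RVF+ 10. The alpha-globin chaperone Ahsp was 2.96-fold, the heme synthesis enzyme Alas2 2.82-fold and Hbb 1.86-fold higher, each above all CON arrays in 4 of 5 arrays. The phosphodiesterase Pde5a was 1.25-fold higher (adjusted p = 0.0217), a call that ended without RVF+ 10 (adjusted p = 0.0688), after quantile normalization (adjusted p = 0.0564) and after centring (adjusted p = 0.104).

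The remaining lists were not called in RVF+ against CON. Neutrophil markers had a median of 0.56 with 0 of 9 genes called by limma and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0915), and passed on ranks (0.0316) and without CON 7 or RVF+ 9, 11 or 12 (the lowest adjusted p being 0.0268). Lymphocyte markers had a median of 0.33 (0.0991, and 0.0363 without RVF+ 10), renin-angiotensin, endothelin and aldosterone genes 0.19 (0.0804, and 0.0200 without RVF+ 12), oxidative stress genes 0.10 (0.136) and endothelial markers 0.093 (0.136). Without RVF+ 8 the median was 0.22 for oxidative stress genes (camera adjusted p = 0.0332) and 0.22 for endothelial markers (camera adjusted p = 0.00818). Medians and adjusted p-values were 0.15 and 0.350 for mast cells, 0.13 and 0.451 for protein degradation, 0.067 and 0.640 for lung epithelium, 0.10 and 0.105 for skeletal muscle, -0.13 and 0.599 for adipocytes and -0.37 and 0.659 for atrial myocardium. For hypoxia and angiogenesis they were 0.11 and 0.869, with a mean of -0.10, and for immediate-early genes -0.10 and 0.543, with a mean of 0.065. The atrial median hides members that moved apart, 3 of 10 being higher and 3 lower. Within CON its markers varied widely, Myl7 from 6.22 to 10.8, Sln from 6.45 to 10.0 and Nppa from 6.35 to 10.2. In RVF+ they ran from 6.09 to 8.24, 4.70 to 7.66 and 11.5 to 12.2. Whether the share of atrial tissue differed between samples was not tested.

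Without RVF+ 8 the comparison gave 2221 genes higher and 2076 lower, and 83.5% of the 4771 calls were kept with 0 in the opposite direction. Centring each array on its median moved the split from 2423 higher and 2348 lower to 1757 higher and 3577 lower, as every difference dropped by 0.094. The median difference over all genes was -0.012 as deposited, -0.0050 after quantile normalization and -0.106 after centring. Centring thus added an offset, which limits what calls that ended with it can show. A single array lay far from the rest of its group for Nppa, Cyp2e1 and Mcam (RVF+ 11), Myh6, Atp2a2, Ppargc1a, Slc2a4, Cyc1 and the oxidative phosphorylation score (RVF+ 8), Tceal7 and Scn4b (CON 4), Adcy1 (CON 2) and Mrc1 (CON 5).

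**Figure D2:**
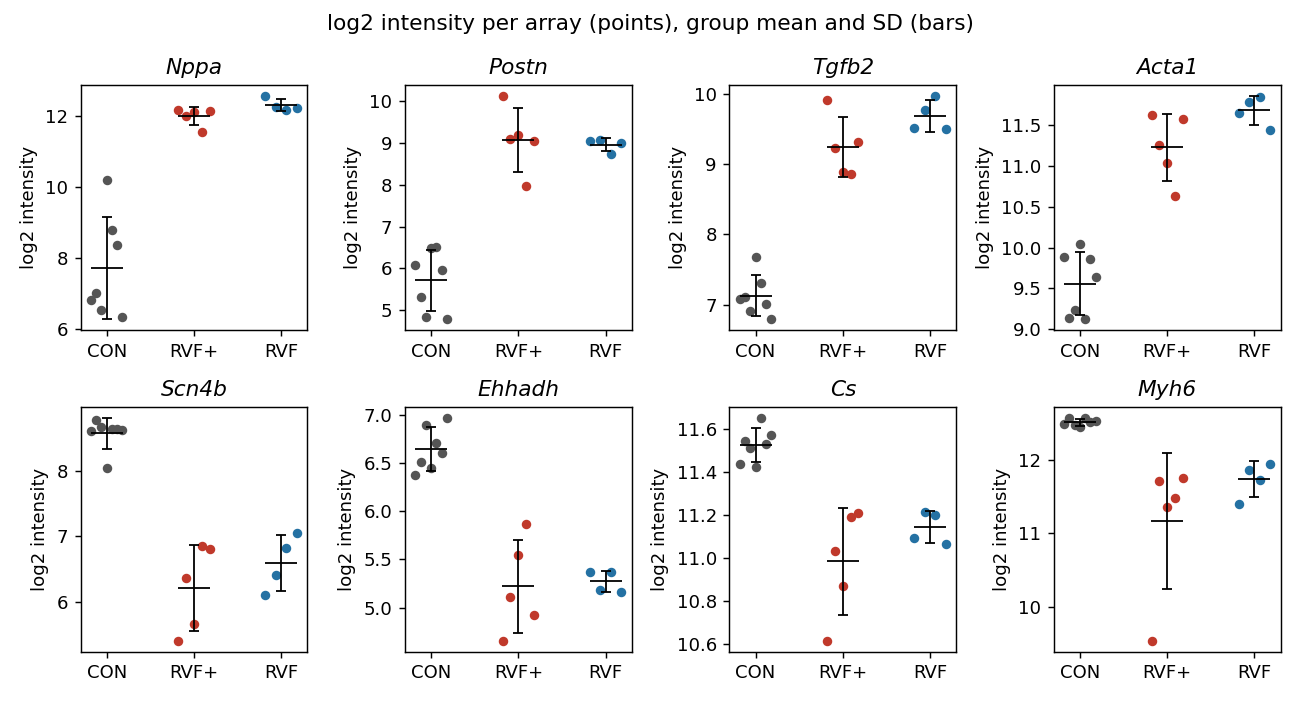
The log2 intensity of 8 genes (vertical axes) in each array, with points for the 7 CON, 5 RVF+ and 4 RVF arrays and bars for the group mean and SD. Nppa, Postn, Tgfb2 and Acta1 lie higher in RVF+ and RVF than in every CON array, and Scn4b, Ehhadh, Cs and Myh6 lie lower, with 1 RVF+ array far below the others for Myh6.

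The second comparison asks how RVF ventricles differed from controls. Here too natriuretic peptides and matrix genes were higher and fatty acid oxidation, calcium handling and ion channel genes lower. Nppa was 23.7-fold higher (4.57 ± 0.54, adjusted p = 1.73e-05), Ankrd23 13.1-fold (3.71 ± 0.31, adjusted p = 8.09e-07) and Thbs4 10.4-fold (3.38 ± 0.39, adjusted p = 1.35e-05), each with 4 of 4 arrays above all CON arrays. Lsamp was 6.15-fold lower (-2.62 ± 0.31, adjusted p = 1.67e-05) and Tmod4 6.03-fold lower (-2.59 ± 0.55, adjusted p = 0.00328), with 4 of 4 arrays below all CON arrays. In all, 1528 genes were higher and 1429 lower, together 17.1% of the genes tested, with 206 higher and 127 lower by at least 2-fold.

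Other large rises were those of Postn (9.54-fold), Tceal7 (8.87-fold), Ltbp2 (8.13-fold), Akip1 (7.89-fold), Ncam1 (7.44-fold), Nppb (6.79-fold) and Tgfb2 (5.88-fold), with adjusted p-values from 3.28e-07 to 4.17e-05. Ddit4l (5.47-fold), Cyp2e1 (5.29-fold), Dhrs7c (5.23-fold), Angpt1 (5.03-fold), Gabrb2 (4.92-fold) and Cacng6 (by a log2 difference of -2.17) fell, with adjusted p-values from 1.67e-06 to 0.000248. All of these stood clear of every CON array in 4 of 4 arrays.

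The cardiac stress programme rose in 16 of 19 cases and fell in 0 (16 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 6.85e-15), and this call held with an estimated correlation (adjusted p = 0.0477). Ccn2 was 4.97-fold, Acta1 4.35-fold and the actin-binding protein Xirp2 2.78-fold higher, and Myh7 rose by 0.87 ± 0.10 (adjusted p = 1.96e-05). Myh6 had a difference of -0.78 ± 0.29 with 4 of 4 arrays below CON but did not pass (adjusted p = 0.0745). It passed without RVF+ 8 in the shared estimate of spread (adjusted p = 1.43e-05), in a fit on the 2 groups alone (2.59e-05) and with array weights (0.000407). Matrix genes rose in 27 of 36 cases and fell in 0 (31 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 1.66e-21, adjusted p = 0.142 with an estimated correlation). Col8a1 was 4.89-fold, the crosslinking enzyme Loxl1 3.59-fold and Bgn 2.54-fold higher, and Col3a1 rose by 0.93 ± 0.19 (adjusted p = 0.00194). Col1a1 rose by 0.79 ± 0.23 (adjusted p = 0.0216), a call that ended without RVF 13 (adjusted p = 0.0541) or RVF 14 (adjusted p = 0.0697). TGF-beta and growth factor genes rose in 10 of 24 cases and fell in 0 (12 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 3.87e-06, adjusted p = 0.163 with an estimated correlation), including Inhba (1.96-fold), Osmr (1.89-fold) and Tgfb1 (1.73-fold). Fibroblast markers rose in 7 of 14 cases and fell in 0 (9 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 1.04e-05, adjusted p = 0.0547 with an estimated correlation), with Thy1 at 3.30-fold and Fap at 2.20-fold. Smooth muscle and pericyte markers rose in 3 of 11 cases and fell in 0 (3 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.00507, adjusted p = 0.310 with an estimated correlation).

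Fatty acid oxidation genes fell in 25 of 30 cases and rose in 0 (28 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.27e-19, adjusted p = 0.226 with an estimated correlation). Ehhadh was 2.59-fold, Eci1 2.06-fold, the thioesterase Acot2 2.04-fold and Crat 1.64-fold lower. Tricarboxylic acid cycle genes fell in 5 of 17 cases (7 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 2.55e-05, adjusted p = 0.472 with an estimated correlation), and in 14 when RVF+ 8 was left out of the shared spread. Oxidative phosphorylation genes fell in 8 of 43 cases (11 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 8.57e-08, adjusted p = 0.504 with an estimated correlation), and in 31 when RVF+ 8 was left out. Cs was 1.30-fold (adjusted p = 0.0113), Ndufs1 1.41-fold (adjusted p = 0.00590) and Pdk4 1.54-fold lower (adjusted p = 0.00980, but 0.0514 without RVF 13). Ppargc1a had -0.63 ± 0.22 with 4 of 4 arrays below CON and did not pass (adjusted p = 0.0533). It passed without RVF+ 8 (adjusted p = 0.000392) or RVF+ 11 (adjusted p = 0.0385), with centring (0.0470), with both filters on dim genes (0.0356 and 0.0444), in a fit on the 2 groups alone (0.000553) and with array weights (0.00121). Slc2a1 rose by 0.42 ± 0.13 (adjusted p = 0.0357), and this call ended with median centring (adjusted p = 0.0852), with all probe sets (adjusted p = 0.0510) and without CON 1, 4 or 6 or RVF 13, 14 or 15, the highest adjusted p being 0.138, without RVF 13.

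Calcium handling and adrenergic genes fell in 17 of 30 cases and rose in 2 (20 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 8.30e-06, adjusted p = 0.310 with an estimated correlation). Trdn, which encodes triadin of the calcium release complex, was 1.83-fold lower, Ppp1r1a 1.77-fold, Pde3a 1.67-fold and Adra1b 1.64-fold. Atp2a2 was 1.28-fold lower (adjusted p = 0.0312), a call that ended without CON 2 or 3 or any 1 of the 4 RVF arrays, the highest adjusted p being 0.0868, without RVF 13. Ion channel and connexin genes fell in 8 of 19 cases and rose in 3 (13 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.0132, adjusted p = 0.472 with an estimated correlation). Scn4b (3.98-fold), Kcnd2 (3.41-fold) and Kcnj5 (1.93-fold) were lower, and the potassium channel subunit Kcne1 was 4.66-fold higher (2.22 ± 0.36, adjusted p = 0.000316). Ttn had -0.12 ± 0.10 (adjusted p = 0.476) and Pde5a 0.15 ± 0.11 (adjusted p = 0.366), and neither passed.

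Cell cycle genes rose in 7 of 25 cases and fell in 0 (14 adjusted over the list alone), with a median of 0.78 (camera adjusted p = 1.07e-06, adjusted p = 0.484 with an estimated correlation), and in 22 cases when RVF+ 8 was left out of the shared spread. Aurkb was 2.98-fold and Mki67 2.64-fold higher, the latter call ending without RVF 15 (adjusted p = 0.0506). Macrophage and monocyte markers rose in 10 of 18 cases and fell in 0 (14 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 4.20e-07, adjusted p = 0.358 with an estimated correlation), among them C1qa (2.06-fold), Adgre1 (2.05-fold) and C1qc (1.91-fold). Without RVF+ 8, 15 of them rose. Interferon response genes rose in 5 of 17 cases (7 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.00135, adjusted p = 0.464 with an estimated correlation), including Isg15 (1.88-fold) and Oas1a (1.54-fold). Oxidative stress and antioxidant genes rose in 7 of 23 cases and fell in 1 (12 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.0230, adjusted p = 0.214 with an estimated correlation). Those that rose included the plasma peroxidase Gpx3 (1.94-fold) and, as sources of oxidants, the NADPH oxidase Nox4 (1.92-fold) and the monoamine oxidase Maoa (1.84-fold). That call ended on ranks (adjusted p = 0.0970) and among genes at or above the median level (adjusted p = 0.0650). Centring reduced the median to 0.073. Lymphocyte markers rose in 4 of 16 cases and fell in 1 (7 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0418, adjusted p = 0.452 with an estimated correlation), Cd4 being 1.65-fold higher and the killer cell receptor Klrd1 1.79-fold lower. This call ended without CON 1 (adjusted p = 0.0502), CON 4 (0.0576), CON 6 (0.0547) or RVF 14 (0.0690).

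Lists not called in RVF against CON were led by sarcomere genes, with a median of -0.11 (camera adjusted p = 0.0509), which passed without CON 1 or 6, RVF+ 8, 11 or 12 or RVF 15 (adjusted p from 0.00767 to 0.0486), in a fit on the 2 groups alone (adjusted p = 0.00675) and on ranks (adjusted p = 0.0159). Medians and adjusted p-values were 0.47 and 0.196 for neutrophils, 0.21 and 0.149 for immediate-early genes, 0.20 and 0.0979 for skeletal muscle, 0.075 and 0.654 for red cell genes, -0.082 and 0.416 for glycolysis and -0.013 and 0.699 for endothelial markers. The other lists not called had medians from -0.18 for atrial myocardium to 0.16 for mast cells. In the atrial list 2 of 10 genes were higher and 4 lower, with Myl7 at 5.67 to 7.26 and Sln at 5.48 to 7.05 in the RVF arrays.

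Leaving out RVF 13 gave 1004 genes higher and 1059 lower, and leaving out RVF+ 8, which changed only the shared estimate of spread here, gave 2315 higher and 1932 lower, among them all 2957 calls. Median centring gave 1084 higher and 2108 lower, and moved the median difference over all genes from -0.0087 to -0.092. A single array lay far from the rest of its group for Akip1, Lsamp and Pde3a (RVF 13) and for Kcne1, Scn4b, Tceal7 and Xirp2 (CON 4).

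The differences of RVF+ and RVF from the controls had much in common. Of the genes that rose in RVF, 81.7% also rose in RVF+ (1248 genes), and of those that fell 88.6% also fell (1266 genes), with 0 in opposite directions. Lists independent of each other would share 215 and 195. Unchanged groups simulated with a shared control group shared 0 in each of 100 draws. Since hardly any gene is called in unchanged groups, this 0 was nearly fixed in advance and says little about the overlap. With the controls split so that the comparisons shared no array, 375 to 786 genes rose in both (median 665.5 over 70 assignments) and 477 to 866 fell in both (median 724.5), with 0 to 3 opposite. Across all 17245 genes, which are not independent replicates, the log2 differences correlated at r = 0.898, against a median of 0.382 (-0.255 to 0.761) in the simulation and 0.808 to 0.847 with split controls. The covariance was 0.119 against a simulated mean of 0.00726, a difference of 0.112, and was 0.111 to 0.117 with split controls. Thbs4 was 10.4-fold higher in both groups, and Nppb was 6.48-fold higher in RVF+ and 6.79-fold higher in RVF.

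**Figure D3:**
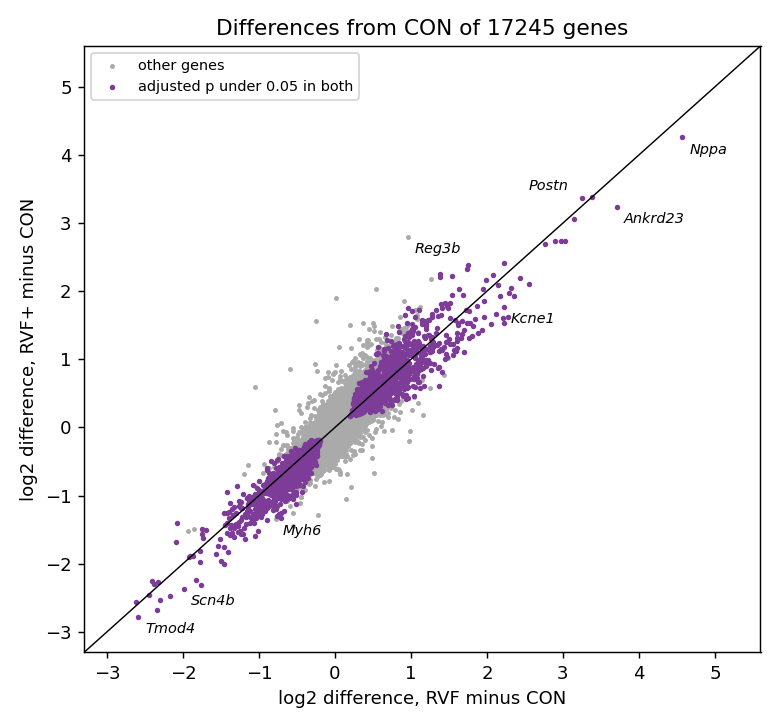
Log2 difference from CON of each of the 17245 genes in RVF (horizontal) and in RVF+ (vertical), with purple points for genes with adjusted p under 0.05 in both and grey points for the rest. The points follow the line of equality (r = 0.898 across genes), with Nppa at the upper end and Tmod4 at the lower end.

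The third comparison asks how RVF+ and RVF ventricles differed from each other. No single gene passed with all arrays. With limma 0 genes were higher and 0 lower, against 1242 genes (7.20%) at an unadjusted p under 0.05, and the smallest adjusted p was 0.289. Fits on the 2 groups alone, with trend and robust moderation or with array weights also gave 0. The median half-width of the 95% confidence interval was 0.24 on the log2 scale. Nppa (-0.31 ± 0.57), Nppb (-0.066 ± 0.38), Postn (0.12 ± 0.38), Myh7 (-0.076 ± 0.11), Col3a1 (-0.17 ± 0.20), Atp2a2 (-0.15 ± 0.12), Ppargc1a (-0.18 ± 0.23), Pde5a (0.17 ± 0.11), Acta1 (-0.45 ± 0.22), Myh6 (-0.56 ± 0.31) and Ttn (-0.25 ± 0.11) were among the genes not called, which does not show that they were equal. RVF+ 8 weighed on several of these values. Without it Postn (-0.14), Myh7 (0.0086) and Ppargc1a (0.10) changed sign, Nppb had -0.13, Col3a1 -0.37, Atp2a2 -0.012 and Myh6 -0.16. Without RVF+ 11 Postn had 0.40, Col3a1 -0.034 and Nppb 0.041.

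The genes with the smallest p, given as values and not as changes, had means higher in RVF+ for Tmem63c (1.17 ± 0.30), the galectin Lgals5 (1.13 ± 0.28), Fkbp5, a co-chaperone of the glucocorticoid receptor (0.99 ± 0.20), Ndrg1 (0.73 ± 0.15) and the nucleoside transporter Slc28a2 (0.65 ± 0.13). Means were lower in RVF+ for the pacemaker channel Hcn4 (-1.05 ± 0.23), the calcium channel Cacna1a (-0.75 ± 0.13), Myocd, a coactivator of muscle genes (-0.59 ± 0.11), Synpo2l (-0.59 ± 0.13) and Samd4a (-0.47 ± 0.10). Their adjusted p-values were 0.289 to 0.403. Without RVF+ 12, 3 genes passed at an adjusted p of 0.0376, namely Slc28a2 (0.74 ± 0.11), Ndrg1 (0.86 ± 0.13) and Ace, which encodes angiotensin-converting enzyme (0.95 ± 0.15), the last chosen after its values were seen. No other array left out gave a call.

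As groups, 13 lists were shifted between RVF+ and RVF by camera at the preset correlation, none of them with a member called over all genes. With an estimated correlation and with fry 0 lists passed. The largest shift was in red cell genes, with a median of 0.56 and 8 of 8 members positive (1 adjusted over the list alone, camera adjusted p = 1.48e-05, adjusted p = 0.310 with an estimated correlation), 0.61 without RVF+ 8 and 0.35 without RVF+ 10. Ahsp had 1.81 ± 0.50 with 4 of 5 RVF+ arrays above all RVF arrays, Alas2 0.97 ± 0.38 and Hbb 0.57 ± 0.25. Ion channels were shifted lower, with a median of -0.30 (4 adjusted over the list alone, camera adjusted p = 1.64e-06, adjusted p = 0.236 with an estimated correlation), and -0.16 without RVF+ 8, Kcnd3 having -0.56 ± 0.15. The cardiac stress programme was lower in RVF+ by a median of -0.20 with and without RVF+ 8 (1 adjusted over the list alone, camera adjusted p = 0.000543, adjusted p = 0.310 with an estimated correlation), Gdf15 having -0.59 ± 0.22 and Xirp2 -0.45 ± 0.18. Endothelial markers had a median of 0.16 (1 adjusted over the list alone, camera adjusted p = 0.0197, adjusted p = 0.538 with an estimated correlation) and 0.24 without RVF+ 8, with Vwf at 0.75 ± 0.20. The call ended without RVF+ 9 (median 0.11, camera adjusted p = 0.0795), RVF+ 10 (0.082, adjusted p = 0.5679), RVF 14 (0.13, adjusted p = 0.0818) or RVF 16 (0.14, adjusted p = 0.0836). It also ended on ranks (adjusted p = 0.0707).

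For the other shifted lists the size depended on RVF+ 8. Tricarboxylic acid cycle genes had a median of -0.21, with Ogdh at -0.33 ± 0.13, or -0.18 without RVF+ 8 (0 adjusted over the list alone, camera adjusted p = 1.55e-06, adjusted p = 0.413 with an estimated correlation). This median was -0.068 without RVF+ 8. Glycolysis genes had -0.17 (0 adjusted over the list alone, camera adjusted p = 0.000214, adjusted p = 0.350 with an estimated correlation) and -0.067 without it. Sarcomere genes had -0.14 (0 adjusted over the list alone, camera adjusted p = 2.55e-05, adjusted p = 0.413 with an estimated correlation) and -0.053 without it. These lists still passed without RVF+ 8 (adjusted p = 0.0259, 0.0372 and 0.0322). The median of calcium handling genes was -0.15, with Adra1b at -0.54 ± 0.14 and Jph2 at -0.39 ± 0.11 (2 adjusted over the list alone, camera adjusted p = 0.00127, adjusted p = 0.413 with an estimated correlation), and the call ended without RVF+ 8 (-0.067, adjusted p = 0.133), while the median was -0.23 without RVF+ 11. TGF-beta and growth factor genes had 0.15 (0 adjusted over the list alone, camera adjusted p = 0.0182, adjusted p = 0.413 with an estimated correlation), a call that ended without RVF+ 8 (0.081, adjusted p = 0.323) or RVF+ 10 (adjusted p = 0.0835) and among genes at or above the median level (adjusted p = 0.403).

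In another 4 lists the median changed sign without RVF+ 8. Cell cycle genes had 0.35 (0 adjusted over the list alone, camera adjusted p = 0.000257, adjusted p = 0.631 with an estimated correlation) and -0.082 without it. Macrophage markers had 0.32, with Mrc1 at 0.66 ± 0.29, or 0.36 without RVF+ 8 (0 adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.519 with an estimated correlation). The median was -0.041 without it. Oxidative phosphorylation genes had -0.13, with Cyc1 at -0.32 ± 0.14, or -0.14 without RVF+ 8 (0 adjusted over the list alone, camera adjusted p = 1.26e-05, adjusted p = 0.627 with an estimated correlation). Without it that median was 0.011. Fatty acid oxidation genes had -0.13, with Crat at -0.20 ± 0.10, or -0.13 without RVF+ 8 (0 adjusted over the list alone, camera adjusted p = 0.0395, adjusted p = 0.788 with an estimated correlation). They had 0.027 without it. Without RVF+ 11 the medians of cell cycle and fatty acid oxidation genes were 0.58 and -0.23. The call of fatty acid oxidation genes also ended without CON 4 (0.0508), RVF+ 10 (0.115), RVF 14 (0.112), RVF 15 (0.0611) or RVF 16 (0.0836), after quantile normalization (0.0851), among genes at or above the median level (0.154) and in a fit on the 2 groups alone (0.0892). Matrix genes were not called, with a median of 0.0098 (adjusted p = 0.628), but were shifted by -0.11 without RVF+ 8 (adjusted p = 0.0441) and by 0.12 without RVF+ 11 (adjusted p = 0.00881). The other lists not called had medians from -0.17 for immediate-early genes to 0.12 for neutrophils. Of these, immediate-early genes passed without RVF+ 10 (-0.29, adjusted p = 0.00362), renin-angiotensin, endothelin and aldosterone genes without RVF+ 12 (0.071, adjusted p = 0.00960) and protein degradation genes without RVF 13 (0.12, adjusted p = 0.0274).

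**Figure D4:**
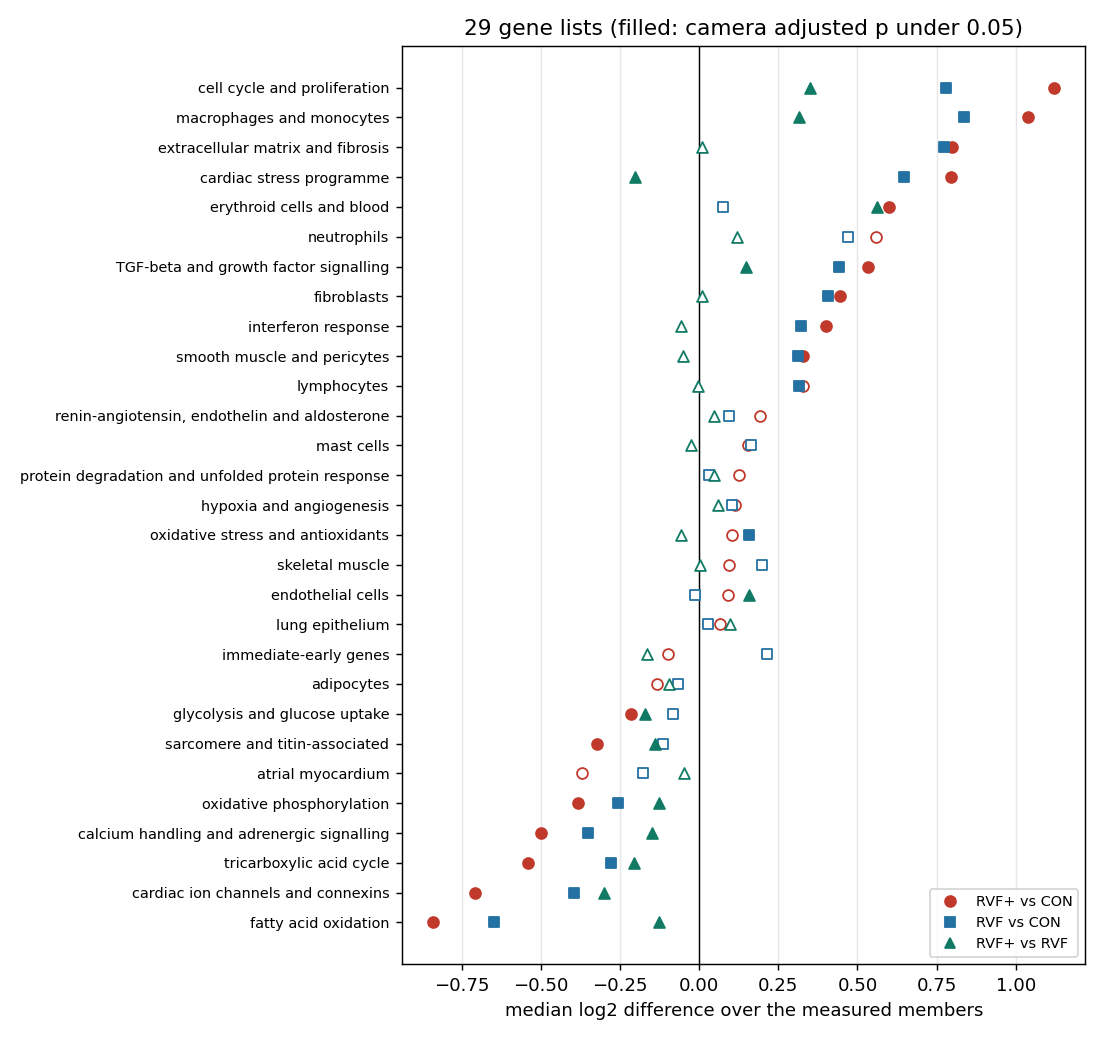
Median log2 difference over the measured members of each of the 29 gene lists (horizontal axis), with circles for RVF+ against CON, squares for RVF against CON and triangles for RVF+ against RVF, filled where the camera adjusted p was under 0.05. Differences from CON run from -0.84 for fatty acid oxidation to 1.12 for cell cycle genes, both in RVF+, and differences between RVF+ and RVF from -0.30 to 0.56.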

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

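The tests of distance from CON and of rank correlation for RVF+ 8 and the test of residual blood with its white cells were chosen only after the results were seen. Values below in which 1 array stood far from its group are given as the gap to the nearest array divided by the range of the group. Of 399 group values examined, 27 (6.77%) stood apart, where chance alone gives about 19.95, so single cases carry little weight.

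RVF+ 8 held 9 of these values and was the array with most of them. They were low for Myh6 (0.824), Atp2a2 (0.765), Cyc1 (0.755), Ppargc1a (0.729) and Slc2a4 (0.713) and for the scores of the oxidative phosphorylation (0.827), hypoxia and angiogenesis (0.760) and mast cell lists (0.739), and high for Adgre1 (0.749). In RVF+ 11, Cyp2e1 (0.822) was high and Mcam (0.841) and Nppa (0.752) were low, and in RVF+ 9 the lung epithelium score was high (0.760). RVF 13 was high for Akip1 (0.967), Tpm3 (0.883) and the glycolysis score (0.845) and low for Lsamp (0.879) and Pde3a (0.922), and RVF 14 was low for Slc2a4 (0.914). Among controls, CON 4 was high for Tceal7 (0.646), Xirp2 (0.614) and Kcne1 (0.601) and low for Scn4b (0.761). CON 2 was high for Adcy1 (0.670), CON 5 for Mrc1 (0.571) and the adipocyte score (0.583), and CON 7 for the protein degradation score (0.636).

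The distance of RVF+ 8 from the other RVF+ arrays was weighed against 3 explanations. Skeletal muscle and lung markers were not raised in it (median -0.15 against the other RVF+ arrays, standard error 0.086 over markers), which argues against those 2 tissues only. Its scores of macrophage (2.20 against 0.60 to 1.09 in the other RVF+ arrays), cell cycle (2.81 against 0.25 to 1.17) and lymphocyte lists (0.74 against -0.020 to 0.34) were high, and a different mix of cells was not tested. Its gap on PC1 was 0.703 as deposited, which is not among the 27 values that stood apart. Quantile normalization left that gap at 0.696 and its root mean square distance from CON at 0.702. This decides nothing, since it moved the array by only 0.069, less than its excess distance of 0.263. Its mean rank correlation with the other RVF+ arrays was 0.968, against 0.984 to 0.989 among those (SD 0.0019). An array-wide scale that keeps the order of values would not lower it. The quantile normalization within RMA should already have removed such a scale, so this outcome was nearly fixed in advance and says little. Any other fault of normalization stays open. Across genes, which are not independent, its deviation correlated at r = 0.477 with the difference between RVF and CON, which shares no array with it, so it may be a larger version of that difference. RNA quality and severity in that animal were not tested. Of the 13 lists shifted between RVF+ and RVF, 7 passed in the same direction without it at the preset correlation. With an estimated correlation and with fry 0 lists passed even with it, so this count cannot show a shift independent of RVF+ 8. Among the 7, the medians of tricarboxylic acid cycle, glycolysis and sarcomere genes shrank to -0.068, -0.067 and -0.053 without it. Those of red cell and endothelial genes did not (0.61 and 0.24). RVF+ 8 may account for part of those shifts.

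The red cell list was higher in RVF+ than in RVF by a median of 0.56. RVF+ 8 alone is argued against, since the median was 0.61 without it. The scores were 0.29, 1.02, 1.43, 0.85 and 0.031 in RVF+ 8 to 12 and 0.64, -0.13, 0.090 and -0.25 in RVF 13 to 16, so the groups overlap. Blood left in the tissue would also bring white cells, and the neutrophil list had a median of 0.12 (standard error 0.080 over markers, not arrays), which lies too near the bound set for it to decide. With no bound set, the lymphocyte list had a median of -0.0033 and the macrophage and monocyte list 0.32 (-0.14 and -0.041 without RVF+ 8). Residual blood and a change in red cell genes thus cannot be told apart. Hbb was already abundant in CON, at 10.8 to 11.1 on the log2 scale.

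Other assignments of the arrays to groups of the same sizes were counted. For RVF+ against CON, 1 of 100 splits, the real one, gave as many as 4771 genes, and the highest of the others gave 1744. For RVF against CON it was also 1 of 100, with 2957 genes against a highest other of 0. In both cases 1 of 100 is the smallest share that these splits allow, so chance is made unlikely but is not excluded. For RVF+ against RVF the observed count was 0, which all 100 splits must reach (the highest 3), so they say nothing about chance.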

How the results depend on the processing

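No paired analysis was possible because no sample number is shared between groups. Counts within 1.5 times the reported ones were found under all settings except those given here, and the cause of a change was not tested unless stated. Median centring, which lowered every difference between RVF+ and CON by 0.094, gave 3577 genes lower in RVF+ than in CON. For RVF against CON, array weights, which gave RVF+ 8 a weight of 0.174, called 2474 genes higher and 2214 lower, and a fit on those groups alone called 2440 higher. A 1.5-fold minimum, stricter by construction, left 1004 and 718 genes in RVF+ and 641 and 473 in RVF against CON. With an estimated correlation 0, 1 and 0 lists were called in RVF+ against CON, RVF against CON and RVF+ against RVF, and with fry 18, 10 and 0. Leaving out single arrays gave 1004 (RVF 13) to 2315 (RVF+ 8) genes higher in RVF than in CON, 0 to 3 (RVF+ 12) higher in RVF+ than in RVF, and 8 (RVF+ 8) to 14 (RVF 13) lists in the latter comparison. With single arrays left out, the correlation of the differences from CON stayed between 0.873 and 0.901. In the same fits, medians between RVF+ and RVF ranged from -0.11 (without RVF+ 8) to 0.12 for matrix, -0.23 to 0.027 for fatty acid oxidation, -0.17 to 0.011 for oxidative phosphorylation, -0.082 to 0.58 for cell cycle and -0.041 to 0.43 for macrophage genes. In each, the end with the changed sign came without RVF+ 8. Centring also turned the matrix median from 0.0098 to -0.00046. No gene described changed direction under any setting where it was called. Of the other values of named genes, 88 of RVF against CON lost and 11 gained a call, against 36 lost in RVF+ against CON and 2 gained between RVF+ and RVF. Of list values that kept their direction, 26, 19 and 43 lost and 9, 12 and 4 gained one in RVF against CON, RVF+ against CON and RVF+ against RVF. Another 5 list values of RVF+ against RVF changed direction, all without RVF+ 8. Of these, matrix genes gained a call, and fatty acid oxidation, oxidative phosphorylation, cell cycle and macrophage genes lost theirs. Signal near background limits all folds of dim genes.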

Other observations

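Another 13 gene lists, with 39 tests among them, were chosen after the data were seen, and only the test of glucocorticoid-responsive genes had its bound set before its result. Mitochondrial ribosomal proteins, which make the proteins encoded in the mitochondrial genome, fell in 31 of 65 cases and rose in 2 in RVF+ against CON (median -0.27, camera adjusted p = 2.48e-09, adjusted p = 0.393 with an estimated correlation). In RVF 16 fell and 1 rose (median -0.21, camera adjusted p = 2.99e-06, adjusted p = 0.533 with an estimated correlation). Mitochondrial carriers, the transporters of the inner membrane, fell in 21 of 43 cases and rose in 6 in RVF+ (median -0.22, camera adjusted p = 0.00165, adjusted p = 0.290 with an estimated correlation). In RVF 12 fell and 3 rose (median -0.19, camera adjusted p = 0.00400, adjusted p = 0.315 with an estimated correlation). In RVF+ the coenzyme A carrier Slc25a42 (-0.93 ± 0.11) and the acylcarnitine carrier Slc25a20 (-0.77 ± 0.10) fell, while Slc25a24 (0.79 ± 0.17), a calcium-regulated carrier, and the ADP/ATP carrier Slc25a5 (0.25 ± 0.075) rose. Cytosolic ribosomal proteins rose in 30 of 157 cases and fell in 3 in RVF+ (median 0.15, camera adjusted p = 8.08e-06, adjusted p = 0.322 with an estimated correlation), and many of them are near-identical to pseudogenes. In RVF 8 rose and 4 fell (median 0.097, camera adjusted p = 0.0197, adjusted p = 0.575 with an estimated correlation). In both comparisons the share of cytosolic ribosomal proteins called was smaller than among all genes, 27.7% in RVF+ and 17.1% in RVF against CON. Without RVF+ 8 the medians in RVF+ against CON were -0.22 for mitochondrial ribosomal proteins, -0.24 for mitochondrial carriers and 0.13 for cytosolic ribosomal proteins. Between RVF+ and RVF, mitochondrial ribosomal proteins had a median of -0.088 (camera adjusted p = 0.000416), cytosolic ribosomal proteins 0.075 (1.06e-05) and cathepsins 0.078 (0.0197). Without RVF+ 8 these medians were -0.040, 0.034 and 0.079, and the smallest adjusted p of the 3 with an estimated correlation was 0.290. The medians of the ribosomal and carrier lists kept their sign after quantile normalization and after centring, but centring reduced that of cytosolic ribosomal proteins to 0.059 in RVF+ and 0.013 in RVF against CON. It turned the medians of cathepsins against CON from 0.082 to -0.012 in RVF+ and from 0.020 to -0.064 in RVF. The lists of clock genes, proteasome subunits, tubulins, further collagens, Adamts proteases, cathepsins, semaphorins and complement were not called against CON, the smallest camera adjusted p being 0.0828 for Adamts proteases in RVF.

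Fkbp5 and Ndrg1, both known to respond to glucocorticoids, were among the genes with the smallest p for higher values in RVF+ than in RVF. A candidate explanation is a stronger glucocorticoid response in RVF+. Over 17 other responsive genes the median difference between RVF+ and RVF was 0.39, above the bound of 0.2 set beforehand, and 0.28 without RVF+ 8. Its standard error of 0.066 is a spread over genes, which may vary together, and not over arrays. Of the 17 genes 16 were positive and 0 called by limma, against 7 at an unadjusted p under 0.05 (camera adjusted p = 5.78e-08, adjusted p = 0.290 with an estimated correlation). Against CON, 11 rose and 1 fell in RVF+ (median 0.74, or 0.65 without RVF+ 8, camera adjusted p = 0.000627, adjusted p = 0.436 with an estimated correlation) and 2 rose and 2 fell in RVF (median 0.26, camera adjusted p = 0.353), with 13 and 9 genes at an unadjusted p under 0.05. Larger differences between RVF+ and RVF included Sult1a1 (1.04 ± 0.32), Zbtb16 (0.89 ± 0.24), Tsc22d3 (0.48 ± 0.19) and Sgk1 (0.43 ± 0.15). The responsive genes Klf9 and Klf15 had differences of only -0.018 ± 0.18 and 0.0037 ± 0.20, several of the listed genes also respond to other stresses, and hormone levels were not analysed here. Clock genes high when Dbp is high had a median of -0.39 between RVF+ and RVF, or -0.25 without RVF+ 8, with 1 of 6 positive (camera adjusted p = 0.0708, adjusted p = 0.648 with an estimated correlation). Those low when Dbp is high had 0.18, or 0.044 without RVF+ 8 (camera adjusted p = 0.420). A difference in time of sampling, which the labels do not give, thus stays open, and the explanation remains a hypothesis.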
